A study of Mus musculus with 70 samples.

How the data were processed

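RNA was measured by sequencing in 70 libraries from 8 mouse cancer cell lines, each left without added cytokine (NS) or kept with interferon beta (IFNb) or interferon gamma (IFNg). The cells grew in DMEM with serum, RNA was taken with Qiagen RNeasy kits and libraries were made with NEB Ultra II Directional kits, per the labels' protocols. Reads were trimmed with Trimmomatic 0.36 and quantified with kallisto against mm10/GRCm38, per the submitters' processing notes, which give no kallisto version. The authors deposited 1 table of estimated counts per gene for all 70 libraries, with no scaling between libraries, and its values were whole numbers. How transcripts were summed to genes was not given in the sources used here. Columns were matched to samples by their titles, and groups were taken from the cell line and treatment in the labels.

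From these estimated counts the fold changes and tests were computed here with edgeR 4.0.16 in R 4.3.3. One quasi-likelihood model held 1 coefficient for each of the 24 groups of line and treatment, so that groups of 2 or 3 libraries shared one estimate of the spread (prior degrees of freedom 9.22). Libraries were scaled by TMM, and 16147 of the 35197 genes passed edgeR's filter on low counts. The 3 kinds of contrast tested were IFNb against NS, IFNg against NS and IFNg against IFNb, each within every line, as the equally weighted mean of the 8 lines, and as an F test that the 8 within-line differences were equal. The error of a mean over lines is the spread between libraries within groups, not the spread between lines. All adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. "Rose" and "fell" stand for an adjusted p under 0.05, and counts over all genes also ask for a change of at least 2-fold. Standard errors (SE) of log2 fold changes were taken as the size of the fold change divided by the square root of its F value.

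Gene lists for 26 themes were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes, apart from additions that the closing section marks. The lists covered antiviral effectors, GBP and IRG GTPases, MHC class I, MHC class II, interferon receptors and signalling, feedback inhibitors, checkpoint ligands and immune evasion, chemokines, nucleic acid sensing, the Slfn and Ly6 families, complement, cell death, NF-kB targets, proliferation, p53 targets and CDK inhibitors, MYC and ribosome biogenesis, cholesterol synthesis, glycolysis and hypoxia, the unfolded protein and stress response, extracellular matrix and TGF-beta targets, melanocyte, epithelial and mesenchymal markers, leukocyte and endothelial markers for other cell types, and mitochondrially encoded genes as a sign of RNA quality. Lists were tested on the 3 means over lines with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and contrasts, with an estimated correlation beside it. The text prints the adjusted p at the preset. It adds that with an estimated correlation where only the preset passed and for some other lists. The latter was often many orders of magnitude larger. Camera compares a list's genes with all other genes tested. Within a line, lists are given as counts and medians without a test. For those medians, a group with 3 or fewer counts over its libraries was set to 3 counts, and members at or under 3 counts in both groups were left out.

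The named genes were, for each mean over lines, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, one sign in all 8 lines and more than 3 counts in both groups of every line. For each line and cytokine, the 2 largest positive departures and the largest negative departure from the mean of the other 7 lines were added, among genes past the test for a difference between lines and for the departure, with more than 3 counts in both groups of the line. Fixed genes were followed in all 8 lines, and from each list up to 4 members with the largest mean change and up to 2 that did not pass were taken. Predicted loci without a gene name were counted, and named only where they led a list. Genes outside this rule are marked as chosen after their values were seen.

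Fitted fold changes of genes with a group near 0 counts depend on the prior and their test on the mean over lines has little power, so such genes are given by line and by level. Levels are CPM after TMM scaling, as mean ± SD over libraries. A fold against a group of 0 counts is a lower bound, taken against a floor of 3 counts over the group. Relations across the 8 lines used Pearson's r and Spearman's rho with exact 2-sided permutation tests in scipy 1.17.1. Gene positions are from the GRCm38 annotation.

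Total estimated counts ran from 668355 (KPC.2 with IFNb, replicate 3) to 28550816 per library, with a median of 8644887, and the floor of 3 counts over a group came to between 0.0389 and 0.335 CPM. Replicates were compared before averaging: over 68 pairs within groups the chi-square statistic per gene ran from 1.53 to 15.7, so none was treated as one library deposited more than once. The model was tested on simulated data with 200 changed genes among 15739 tested genes. Counts were drawn from the trend of the dispersion, without a spread of its own for each gene. The changed genes were picked above a minimum mean count and changed alike in every line. Recovery in the real data may therefore be lower. For IFNb against NS in B16.1 it recovered 72% of genes changed 2-fold and 84% of those changed 4-fold, with 5 unchanged genes called before the fold condition. In Renca 11 unchanged genes were called, the most of any line. For the mean of 8 lines it recovered 78% and 85%, with 7 unchanged genes called.

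The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors within edgeR, no filter on low counts, each line fitted alone, the replicate number as a block, and leaving out each library in turn. Refits that left out a library or regrouped the libraries kept the trend of the negative binomial dispersion and estimated the quasi-likelihood dispersion again. Nothing was left out for quality. The text names genes that share sequence with close relatives (the Gbp, Iigp1, Tgtp1, Apol9, Oas1 and H2 families, and Pgk1-rs7) with the limit that kallisto may divide reads between them.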

Results

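The data were transcript counts of 8 mouse cancer cell lines 48 hours after stimulation with IFNb (1000 activity units per mL) or IFNg (100 ng per mL), or without either. B16.1 and YUMMER1.7 were melanoma lines, CT26.2 and MC38.7 colorectal, KPC.2 and Panc02.3 pancreatic, LLC lung and Renca renal cancer lines. CT26.2 and Renca came from BALB/c mice and the other 6 from C57BL/6. Of the 24 groups, 22 held 3 libraries, while LLC with IFNg and unstimulated Renca held 2 each. Group sums ran from 8749483 counts (KPC.2 with IFNb) to 75811551 (MC38.7 with IFNg). The labels do not mark replicates as separate cultures, so the p-values measure the spread between these libraries, which may be technical. The comparisons ask what each cytokine did to transcript levels in each line, how the 2 cytokines differed, and where the lines differed from each other.

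IFNb raised genes of antiviral defence and of antigen presentation in 7 lines, while YUMMER1.7 changed little. On the mean of the 8 lines the log2 rise was 5.35 ± 0.07 (SE, 24 IFNb and 23 NS libraries) for Oas1a, which makes 2',5'-oligoadenylates against viral RNA, 5.30 ± 0.05 for Irf7, a transcription factor of the type I interferon response, and 2.72 ± 0.04 for Tap1, which carries peptides to MHC class I. H2-K1 rose by 2.23 ± 0.03 and its partner B2m by 1.88 ± 0.02, and both rose in all 8 lines. The adjusted p was 1.2e-55 for Oas1a, 1.4e-61 for Irf7 and 4.5e-51 for Tap1 in edgeR's quasi-likelihood test. Among genes with the same sign in all 8 lines and more than 3 counts in every group, falls included Ankrd37 (−0.97 ± 0.18), Kazald1 (−0.80 ± 0.12) and the acetyl-CoA synthetase Acss2 (−0.66 ± 0.06).

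Of 38 antiviral effectors, 37 rose and 0 fell on the mean of the lines (camera adjusted p = 3.0e-131, adjusted p = 7.0e-07 with an estimated correlation). Among them were Ifit1 (4.60 ± 0.06) and Isg15 (4.23 ± 0.05). Cmpk2 did not pass, being near 0 counts in some unstimulated lines. Of 17 GBP and IRG GTPases, which act on vacuoles of intracellular pathogens, 15 rose (adjusted p = 5.2e-47), with Gbp3 at 5.26 ± 0.05. Of 23 MHC class I genes, 21 rose (adjusted p = 6.5e-53), and the chaperones Canx (−0.03 ± 0.02) and Calr (−0.02 ± 0.02) did not pass. None of 11 MHC class II genes passed (adjusted p = 0.90). In the signalling list 9 of 17 rose and 2 fell (adjusted p = 3.8e-09), with Stat2 at 2.12 ± 0.04 and the receptor subunit Ifnar1 at −0.15 ± 0.02. Of 12 feedback inhibitors 4 rose and 1 fell (adjusted p = 0.038), led by Usp18 (4.84 ± 0.06) and Socs1 (0.92 ± 0.10). Of 15 checkpoint and immune evasion genes 7 rose (adjusted p = 1.8e-07), with Lgals9 at 2.31 ± 0.03 and Cd274, which encodes PD-L1, at 1.53 ± 0.05. Nucleic acid sensors rose in 11 of 17 (adjusted p = 3.5e-24), led by Trim30a (4.57 ± 0.06), and the Slfn and Ly6 list, which also holds the galectin-3-binding protein gene Lgals3bp (2.25 ± 0.02), in 8 of 11 (adjusted p = 1.1e-10).

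Weaker shifts on the mean of the lines were spread over other lists and need not hold in every line. In edgeR's F test the response differed between lines for 26 of 26 proliferation, 17 of 17 glycolysis and 19 of 20 cholesterol synthesis genes. It did so for 14 of 16 MYC, 22 of 25 cell death, 11 of 13 mitochondrially encoded, 10 of 17 NF-kB and 7 of 11 complement genes. Cell death genes rose in 15 of 25 and fell in 2 (adjusted p = 2.8e-06), with the death ligand gene Tnfsf10 at 2.53 ± 0.20 (7 lines above 3 counts), and NF-kB targets rose in 6 of 17 (adjusted p = 6.8e-04), with Csf1 at 0.89 ± 0.02. MYC and ribosome biogenesis genes rose in 14 of 16 by small amounts (adjusted p = 9.4e-12, adjusted p = 0.019 with an estimated correlation), with Myc at 0.36 ± 0.02. Cholesterol synthesis genes fell in 15 of 20 (adjusted p = 1.0e-11, adjusted p = 0.0022 with an estimated correlation), with Mvd at −0.39 ± 0.04 and Lss at −0.35 ± 0.03. Complement rose in 4 of 11 (adjusted p = 0.021), led by C4b (1.27 ± 0.13), but its adjusted p = 0.071 with an estimated correlation. Glycolysis and hypoxia genes fell in 15 of 17 (adjusted p = 4.8e-10), with Bnip3 at −0.85 ± 0.10 and Pdk1 at −0.64 ± 0.06, and proliferation genes rose in 13 of 26 and fell in 1 (adjusted p = 2.9e-05), with Ccnd1 at 0.27 ± 0.02. The adjusted p = 0.11 with an estimated correlation for glycolysis and 0.16 for proliferation. Mitochondrially encoded genes fell in 11 of 13 (adjusted p = 2.4e-06, adjusted p = 0.16 with an estimated correlation), with mt-Cytb at −0.49 ± 0.06.

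The other lists did not pass camera for IFNb. Chemokines rose in 4 of 15 (adjusted p = 0.22), with Cxcl10, which attracts T cells, at 3.23 ± 0.12. Members that rose and fell numbered 2 and 4 of 14 for p53 targets (adjusted p = 0.62), 3 and 5 of 14 for the unfolded protein response (adjusted p = 0.62), and 5 and 0 of 22 for extracellular matrix (adjusted p = 0.13), where Thbs1 reached 0.93 ± 0.05. They were 1 and 1 of 15 for melanocyte (adjusted p = 0.93), 2 and 0 of 14 for epithelial (adjusted p = 0.62) and 0 and 1 of 10 for mesenchymal markers (adjusted p = 0.94). No tested leukocyte (4 genes, adjusted p = 0.90) or endothelial marker (3 genes, adjusted p = 0.92) changed, and the other 14 and 5 listed markers were too low to test. Adjusted over the list alone, counts differed only for nucleic acid sensing (14 rose), signalling (3 fell), cell death (3 fell), proliferation (15 rose), cholesterol synthesis (17 fell) and glycolysis (16 fell). For p53 targets the median and mean were above 0 and the test pointed down, and for melanocyte markers both were below 0 and the test pointed up. For the unfolded protein and endothelial lists only the mean was above 0.

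By line, IFNb changed 1138 genes at least 2-fold in LLC (746 risen, 392 fallen), 715 in B16.1 (581 and 134), 692 in MC38.7 (534 and 158), 231 in Renca (111 and 120), 218 in KPC.2 (201 and 17), 211 in Panc02.3 (174 and 37), 59 in CT26.2 (40 and 19) and 27 in YUMMER1.7 (9 and 18). On the mean of the lines 272 genes changed (232 risen, 40 fallen). No gene rose 2-fold in all 8 lines with edgeR, nor at an unadjusted p under 0.05 (0 genes), nor with DESeq2 or limma-voom (0 each). In at least 7 lines 17 genes rose, including Irf7, Ifit1, Ifit3, Gbp3, Gbp7, Psmb9, Zbp1 and Iigp1, the missing line being YUMMER1.7 for Irf7. Ankrd37 and Selenbp1 fell 2-fold in at least 4 lines, named after their values were seen, and the number of such genes was 8 without the filter on low counts, 1 with each line fitted alone and 1 when any 1 of 3 libraries was left out. Without the filter on low counts the number was 133 in CT26.2, 135 in YUMMER1.7 and 320 in Panc02.3, with each line fitted alone it was 36 in CT26.2, and with limma-voom 43 in YUMMER1.7. In Renca more genes rose than fell with the replicate block (106 and 89), without the filter (170 and 144) and with each line fitted alone (114 and 108). KPC.2 with IFNb held the shallowest library.

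**Figure D1:**
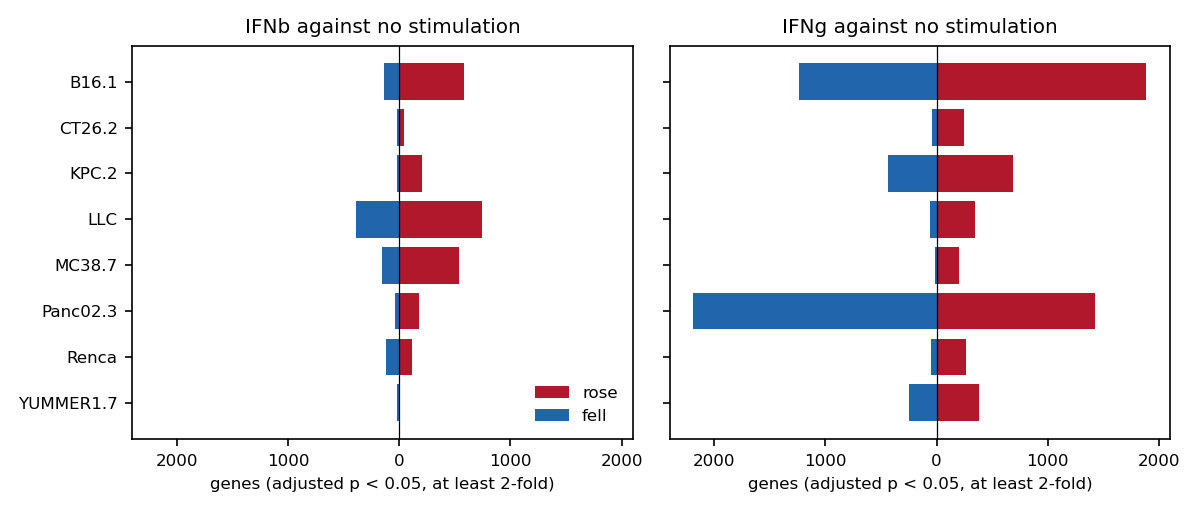
Number of genes changed at least 2-fold (edgeR adjusted p under 0.05) in each of the 8 lines, risen to the right of 0 and fallen to the left, for IFNb against NS and IFNg against NS. IFNg in Panc02.3 gave 1424 risen and 2190 fallen genes, while IFNb in YUMMER1.7 gave 9 and 18.

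IFNg raised GBP and IRG GTPases, MHC class I genes and Cxcl10 in every line. The mean log2 rise was 7.94 ± 0.04 (SE, 23 IFNg and 23 NS libraries) for Gbp2 and 7.41 ± 0.04 for Igtp, GTPases of cell-autonomous defence, 5.55 ± 0.07 for the complement component C4b and 4.85 ± 0.08 for Cxcl10. Cd274 rose by 4.03 ± 0.04 and the transcription factor Irf1 by 3.80 ± 0.03, each in all 8 lines. The adjusted p was 7.5e-75 for Gbp2 and 3.2e-70 for Irf1 in edgeR's test. Among genes with the same sign in all 8 lines and more than 3 counts in every group, falls included Npnt, an extracellular matrix protein (−1.58 ± 0.19), S100a4 (−1.07 ± 0.10), which fell in 7 lines, and the focal adhesion gene Tns1 (−1.03 ± 0.07). On GRCm38, Gbp2 lies on chromosome 3 (142620602 to 142638008), Igtp on chromosome 11 (58199556 to 58207591), Cd274 on chromosome 19 (29367455 to 29388095) and Irf7 on chromosome 7 (141262706 to 141266481).

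All 17 GBP and IRG GTPases rose with IFNg on the mean of the lines (camera adjusted p = 3.0e-57), as did all 38 antiviral effectors (adjusted p = 1.9e-65), with Oasl2 at 4.86 ± 0.06 and Ifit3 at 4.48 ± 0.06. Of 23 MHC class I genes 21 rose and 1 fell (adjusted p = 4.5e-51), with Tap1 at 4.69 ± 0.04 and H2-K1 at 3.27 ± 0.03. In the signalling list 11 of 17 rose and 4 fell (adjusted p = 7.2e-12), with Stat2 at 2.81 ± 0.04 and the receptor subunit Ifngr1 at −0.27 ± 0.03. Nucleic acid sensors rose in 13 of 17 (adjusted p = 9.7e-17), with Ifi203 at 3.50 ± 0.09, and the Slfn and Ly6 list in 10 of 11 (adjusted p = 6.9e-12). Complement rose in 7 of 11 (adjusted p = 5.0e-05), with C1ra at 1.93 ± 0.05. Checkpoint and immune evasion genes rose in 9 of 15 (adjusted p = 5.1e-07), with Tnfrsf14 at 2.45 ± 0.13, and cell death genes in 16 of 25, with 3 fallen (adjusted p = 2.8e-10) and Casp4 at 2.63 ± 0.07. NF-kB targets rose in 8 of 17 (adjusted p = 6.2e-04), with Csf1 at 1.06 ± 0.02.

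Feedback inhibitors rose in 4 of 12 and fell in 2 with IFNg (adjusted p = 0.046, adjusted p = 0.053 with an estimated correlation and 0.065 with the replicate number as a block). Of these, Socs1, which inhibits JAK kinases, rose by 3.67 ± 0.06 and Socs3 by 1.03 ± 0.04, while Pias3 fell (−0.35 ± 0.03). Cholesterol synthesis genes fell in 19 of 20 (adjusted p = 1.5e-15), with Insig1 at −0.76 ± 0.03, but the median was −2.06 in Panc02.3 and −1.10 in B16.1 and between −0.29 and 0.17 in the other 6 lines. Unfolded protein response genes rose in 10 of 14 and fell in 1 (adjusted p = 6.3e-06), with the stress factor Ddit3 at 1.17 ± 0.06 and Trib3 at 0.84 ± 0.07. MYC and ribosome biogenesis genes rose in 15 of 16 and fell in 1 (adjusted p = 5.5e-11, adjusted p = 0.025 with an estimated correlation). Their median was 2.21 in Panc02.3 and between −0.41 and 0.21 in the other 7 lines. Proliferation genes fell in 21 of 26 and rose in 2 (adjusted p = 2.0e-05, adjusted p = 0.16 with an estimated correlation), with Mki67 at −0.52 ± 0.04 and Ccnd1 at 0.36 ± 0.02, and the median was −1.97 in B16.1 and between −0.03 and 0.28 in the other 7 lines. Mitochondrially encoded genes fell in 11 of 13 (adjusted p = 1.9e-04, adjusted p = 0.29 with an estimated correlation), with mt-Nd3 at −0.54 ± 0.08.

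Lists that did not pass camera for IFNg on the mean of the lines were MHC class II (4 rose and 1 fell of 11, adjusted p = 0.17), chemokines (5 rose of 15, adjusted p = 0.073), p53 targets (4 rose and 4 fell of 14, adjusted p = 0.89), glycolysis (4 rose and 10 fell of 17, adjusted p = 0.27) and extracellular matrix (2 rose and 6 fell of 22, adjusted p = 0.36), where Col1a1 stood at −1.16 ± 0.19. Counts of risen and fallen members were 2 and 2 of 15 for melanocyte (adjusted p = 0.98), 1 and 0 of 14 for epithelial (adjusted p = 0.76) and 1 and 1 of 10 for mesenchymal markers (adjusted p = 0.67). They were 1 and 0 of 4 for leukocyte (adjusted p = 0.58) and 0 of 3 for endothelial markers (adjusted p = 0.90), the leukocyte gene being Cd68 (0.36 ± 0.09), with 31 counts in unstimulated B16.1 and 324 with IFNg. Ptprc, a pan-leukocyte gene that was too low to test, stayed at or below 6 counts in every group. Adjusted over the list alone, counts differed only for cell death (4 fell), p53 targets (5 rose) and melanocyte markers (1 rose and 1 fell). The median of the feedback, p53 and epithelial lists was below 0 while the mean and the test pointed up, and for melanocyte markers the median and mean were below 0 and the test pointed up.

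**Figure D2:**
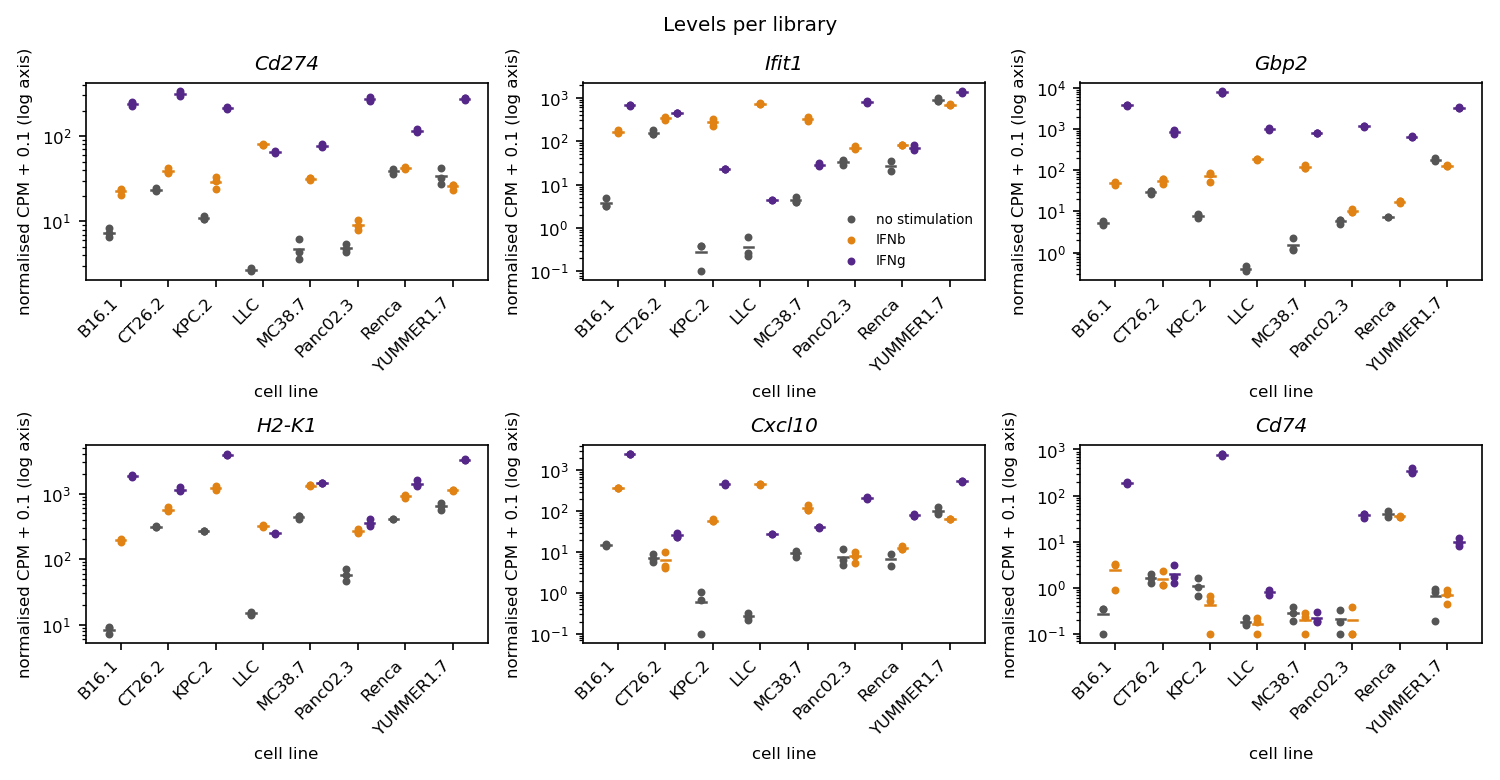
Levels (CPM + 0.1, log axis) of Cd274, Ifit1, Gbp2, H2-K1, Cxcl10 and Cd74 in each library of the 8 lines, by treatment, with the mean of each group. Gbp2 rises from 5.17 to 3836 CPM with IFNg in B16.1 and from 182 to 3343 in YUMMER1.7, where Ifit1 stands at 892 CPM without added cytokine.

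MHC class II genes were near 0 counts in most unstimulated lines and differed between lines with IFNg. Cd74, the invariant chain, went from 1.01 ± 0.485 to 767 ± 51.6 CPM (SD, n = 3) in KPC.2 and from 0.165 ± 0.143 to 187 ± 8.61 in B16.1. In Renca, where the unstimulated level was 40.3 ± 8.09 CPM (n = 2), it reached 345.5 ± 48.2. In CT26.2 and MC38.7 it did not pass (log2 0.30 ± 0.54 and −0.52 ± 0.84), and the difference between lines had an adjusted p of 3.5e-29 in edgeR's F test. Ciita, the transactivator of these genes, had 2 counts in unstimulated KPC.2 and 215 ± 5.05 CPM with IFNg, and H2-Ab1 had 0 counts there and 158 ± 12.4 CPM. The T cell chemokine Cxcl9 reached 762 ± 34.3 CPM in B16.1 and 413 ± 18.0 in KPC.2 with IFNg from 1 and 5 counts, while CT26.2 had 0 counts unstimulated and 2 with IFNg. Ido1, which degrades tryptophan, reached 317 ± 11.1 CPM in KPC.2 from 1.95 ± 0.352, with 0 counts in B16.1 under any treatment.

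By line, IFNg changed 3614 genes at least 2-fold in Panc02.3 (1424 risen, 2190 fallen), 3119 in B16.1 (1883 and 1236), 1124 in KPC.2 (689 and 435), 633 in YUMMER1.7 (382 and 251), 402 in LLC (345 and 57), 312 in Renca (265 and 47), 289 in CT26.2 (249 and 40) and 218 in MC38.7 (202 and 16). On the mean of the lines 525 genes changed (399 risen, 126 fallen). In all 8 lines 73 genes rose 2-fold (82 at an unadjusted p), among them 16 of 17 GBP and IRG GTPases, 16 of 23 MHC class I genes and 3 of 38 antiviral effectors. In at least 4 lines 10 genes fell, namely Acsbg1, Col6a1, Csdc2, Gpm6b, Htra3, Megf10, Nrep, Prelp, Slc40a1 and Stra6, given after their values were seen. That number was 21 without the filter and 5 with each line fitted alone.

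Panc02.3 and B16.1 changed programmes outside the interferon lists with IFNg. In Panc02.3 all 16 MYC and ribosome biogenesis genes rose (median log2 2.21), with Rrp12 at 2.54 ± 0.12 (SE, n = 3 and 3) and Myc at 2.24 ± 0.06. There 19 of 20 cholesterol synthesis genes fell (median −2.06), with Insig1 at −3.07 ± 0.10, 17 of 22 extracellular matrix genes fell (median −1.23), with Col1a1, the main fibrillar collagen chain, at −5.12 ± 0.13, and 11 of 13 mitochondrially encoded genes fell (median −0.57). The proapoptotic gene Bmf stood at −5.77 ± 0.22 and the actin regulator Avil at 6.35 ± 0.27. In B16.1, 25 of 26 proliferation genes fell (median −1.97), with Mki67 at −3.40 ± 0.13 and the CDK inhibitor Cdkn1a at 1.43. The mitochondrially encoded share of counts there was 1.75 to 2.08% unstimulated and 2.82 to 2.97% with IFNg, and of 13 such genes 6 rose and 3 fell (median 0.18). In B16.1 12 of 15 melanocyte markers fell and 1 rose (median −1.53), with Mitf, the regulator of the melanocyte lineage, at −1.53, and 19 of 20 cholesterol synthesis genes fell (median −1.10). Proliferation medians in the other 7 lines lay between −0.03 (Panc02.3) and 0.28 (KPC.2), and all 26 proliferation genes passed the test for a difference between lines. Lists within a line were not tested as sets.

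At the doses and time used, the cytokines differed in which defence genes they favoured. Their doses were given in different units, and neither dose nor time was varied. The contrasts of IFNg with IFNb therefore cannot separate the kind of cytokine from its effective dose or the time of sampling. On the mean of the lines IFNg exceeded IFNb for Gbp4 (log2 5.03 ± 0.04, SE, 23 IFNg and 24 IFNb libraries), Batf2, a transcription factor of interferon-activated cells (4.89 ± 0.06), Gbp2 (4.88 ± 0.03), C4b (4.28 ± 0.06) and Irf1 (3.04 ± 0.02), each in all 8 lines. The predicted locus Gm4841 stood at 5.94 ± 0.06. The adjusted p was 3.0e-70 for Gbp2 and 2.1e-66 for Irf1 in edgeR's test. Antiviral effectors were on the mean lower with IFNg, as for Oas2 (−1.96 ± 0.05) and Oasl1 (−1.74 ± 0.05), and so was Irf7 (−1.48 ± 0.03). Genes below 0 in all 8 lines with more than 3 counts in every group included Tns1 (−1.15 ± 0.08) and Masp1 (−1.09 ± 0.13), a protease of the lectin pathway of complement.

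With IFNg against IFNb, 28 of 38 antiviral effectors were lower and 7 higher (camera adjusted p = 2.6e-21, adjusted p = 0.0048 with an estimated correlation). All 17 GBP and IRG GTPases were higher (adjusted p = 4.4e-67). So were 21 of 23 MHC class I genes (adjusted p = 1.1e-51), with Psmb9, a subunit of the immunoproteasome, at 3.25 ± 0.04. In the signalling list 10 of 17 were higher and 4 lower (adjusted p = 5.4e-06), with Stat3 at 1.10 ± 0.02. Complement was higher in 6 of 11 (adjusted p = 3.2e-05), cell death in 13 of 25 with 4 lower (adjusted p = 3.3e-09), and checkpoint genes in 7 of 15 with 3 lower (adjusted p = 0.018), Cd274 standing at 2.50 ± 0.03. Unfolded protein response genes were higher in 12 of 14 (adjusted p = 6.5e-10), with Trib3 at 0.86 ± 0.08. Proliferation genes were lower in 24 of 26 and higher in 2 (adjusted p = 2.5e-15), with Plk1 at −0.43 ± 0.04, and cholesterol synthesis genes lower in 14 of 20 (adjusted p = 1.1e-08). The proliferation median was −1.91 in B16.1 and between −0.19 and 0.25 in the other lines, and the cholesterol median was −1.90 in Panc02.3 and −0.53 in B16.1 and between −0.20 and 0.34 in the others. The next 4 lists passed only at the preset correlation. Nucleic acid sensors were higher in 7 of 17 and lower in 2 (adjusted p = 0.010, adjusted p = 0.16 with an estimated correlation), and MYC genes higher in 11 of 16 and lower in 1 (adjusted p = 0.0083, adjusted p = 0.40 with an estimated correlation), with a median of 1.95 in Panc02.3 and at most 0.02 in the other lines. Glycolysis genes were higher in 10 of 17 (adjusted p = 8.3e-05, adjusted p = 0.34 with an estimated correlation), with Hk2 at 0.63 ± 0.03, and extracellular matrix genes lower in 9 of 22 and higher in 1 (adjusted p = 0.0045, adjusted p = 0.15 with an estimated correlation), with Thbs1 at −0.66 ± 0.05.

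Between the cytokines the other lists did not pass camera. Higher and lower members numbered 4 and 1 of 11 for MHC class II (adjusted p = 0.17), 3 and 5 of 12 for feedback inhibitors (adjusted p = 0.95), 4 and 0 of 15 for chemokines (adjusted p = 0.12), 3 and 5 of 11 for the Slfn and Ly6 families (adjusted p = 0.90), 7 and 0 of 17 for NF-kB targets (adjusted p = 0.079) and 4 and 2 of 14 for p53 targets (adjusted p = 0.32). They numbered 1 and 1 of 15 for melanocyte (adjusted p = 0.90), 0 and 1 of 14 for epithelial (adjusted p = 0.90) and 1 and 1 of 10 for mesenchymal markers (adjusted p = 0.90). Of 4 leukocyte markers 1 was higher (adjusted p = 0.67), and 0 of 3 endothelial (adjusted p = 0.93) and 0 of 13 mitochondrially encoded genes (adjusted p = 0.74) differed with edgeR. Feedback inhibitors were split, with Socs1 at 2.75 ± 0.06 and Usp18 at −1.63 ± 0.04. Adjusted over the list alone, counts differed for MHC class I (22 higher), nucleic acid sensing (8), cell death (14), glycolysis (11) and epithelial markers (0 lower). For the feedback and Slfn lists the mean lay above 0 with the median and test below, and for p53 targets and mesenchymal markers the mean lay below 0 while the test pointed up.

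The direction of the antiviral list between cytokines differed by line. Its median log2 difference of IFNg from IFNb was −3.87 in LLC (37 of 38 lower), −3.41 in MC38.7 (37 lower) and −1.72 in KPC.2 (31 lower), against 2.03 in B16.1 (34 higher), 0.78 in Panc02.3 (29 higher) and 0.76 in YUMMER1.7 (35 higher). In CT26.2 (0.28) and Renca (−0.07) it lay near 0. Ifit1 went from −7.41 ± 0.16 in LLC to 3.52 ± 0.10 in Panc02.3 (difference between lines, adjusted p = 1.9e-50 in edgeR's F test), and Cxcl10 from −4.05 ± 0.14 in LLC to 4.79 ± 0.16 in Panc02.3. All 38 members passed the test for a difference between lines. Cd274 was higher with IFNg in 7 lines and lower in LLC (−0.30 ± 0.08).

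By line, 3318 genes differed 2-fold between the cytokines in Panc02.3 (1317 higher with IFNg, 2001 lower), 2293 in B16.1 (1258 and 1035), 776 in KPC.2 (492 and 284), 737 in LLC (250 and 487), 591 in YUMMER1.7 (413 and 178), 497 in MC38.7 (155 and 342), 236 in Renca (203 and 33) and 158 in CT26.2 (147 and 11). On the mean of the lines 327 differed (228 and 99). The number was 255 in CT26.2 without the filter (180 and 75). With limma-voom it was 852 in MC38.7 (165 and 687) and 1284 in KPC.2 (497 and 787), where more genes were then lower than higher with IFNg.

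**Figure D3:**
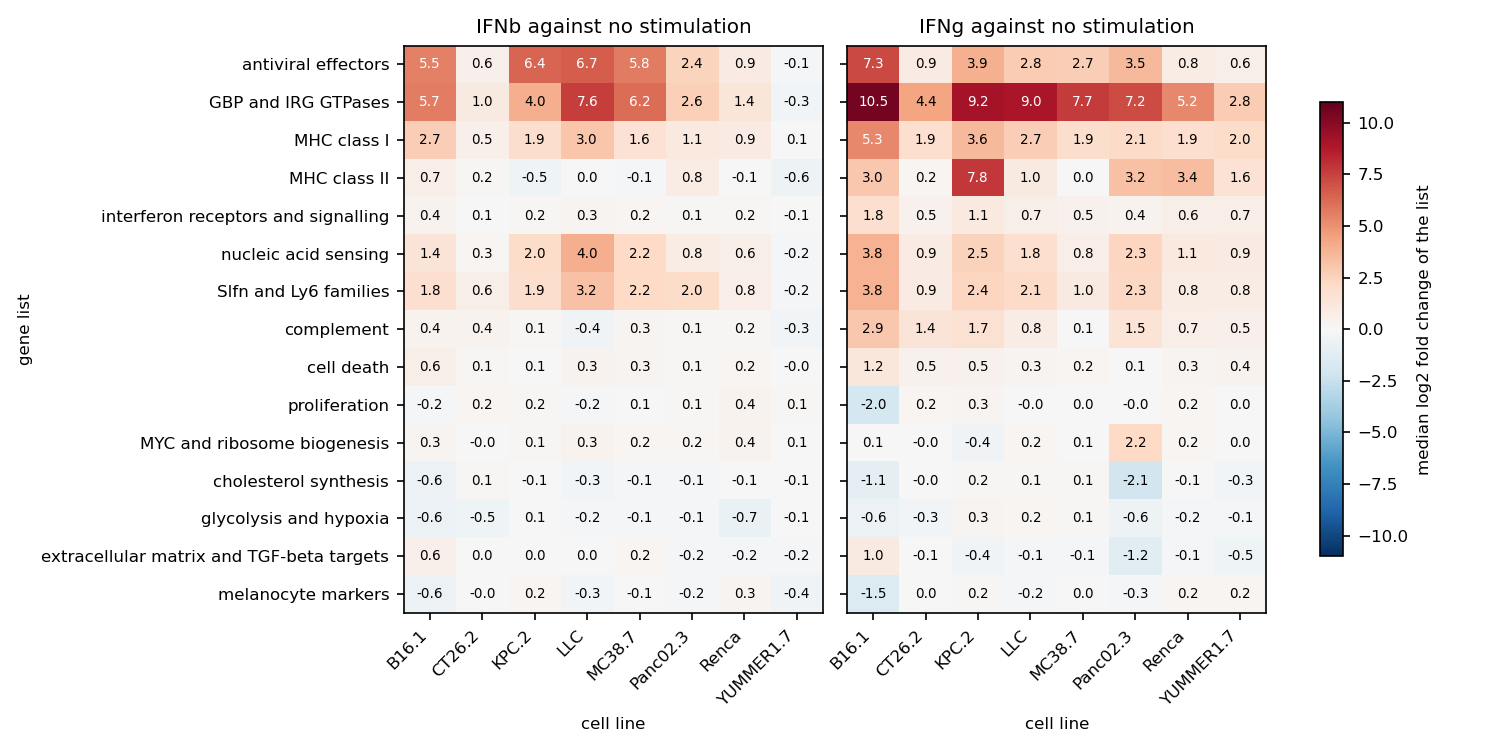
Median log2 fold change of 15 gene lists in each of the 8 lines for IFNb against NS and IFNg against NS, with groups at or under 3 counts set to 3 counts. The antiviral list runs from −0.12 (YUMMER1.7) to 6.69 (LLC) with IFNb, and the GBP and IRG list from 2.78 (YUMMER1.7) to 10.54 (B16.1) with IFNg.

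Lines differed in the size of the response for most interferon genes. With IFNb the antiviral median was 6.69 in LLC, 6.40 in KPC.2, 5.75 in MC38.7, 5.53 in B16.1, 2.44 in Panc02.3, 0.91 in Renca, 0.57 in CT26.2 and −0.12 in YUMMER1.7, where 1 of 38 members rose and 6 fell. With IFNg it ran from 0.61 (YUMMER1.7) to 7.29 (B16.1). The MHC class I median with IFNg ran from 1.85 (Renca) to 5.31 (B16.1), and H2-K1 in B16.1 went from 8.23 ± 0.987 to 193 ± 8.28 CPM with IFNb and 1864 ± 79.5 with IFNg (SD, n = 3). Over all 16147 genes, 7786 differed between lines in their response to IFNb, 11171 in their response to IFNg and 11325 in the difference between the cytokines (adjusted p under 0.05 in edgeR's F test with 7 degrees of freedom). In Renca 16 of 17 glycolysis and hypoxia genes fell with IFNb (median −0.72), and 14 fell in B16.1 (−0.64) and 10 in CT26.2 (−0.50), against 0 in KPC.2 and YUMMER1.7.

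Genes changed at least 2-fold by both cytokines on the mean of the lines went in the same direction. Of these genes, 202 changed with both, 187 risen, 15 fallen and 0 in opposite directions, where independent lists would share 5.73 risen and 0.312 fallen. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.683, beside 0.455 (at most 0.476) in 20 simulations with no effect, and their covariance was 0.232 beside 0.0181. In these simulations at most 0 genes changed with both, which argues against the shared controls as sole cause of the overlap. The simulations held no changed genes and no spread of its own for each gene. The NS groups of 2 or 3 libraries could not be split into parts of at least 2, so part of the excess may still come from the shared controls.

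Across the 8 lines, no relation of receptor levels before stimulation to the response passed. With only 8 lines this does not show that there was none. The response of a line was taken here as the median of the fitted log2 fold changes of a list. Against the IFNb response of the antiviral list r was 0.173 for Ifnar1 and −0.226 for Ifnar2, the subunits of the IFNb receptor. Against the IFNg response of MHC class I it was −0.084 for Ifngr1 and 0.648 for Ifngr2, the subunits of the IFNg receptor. The IFNb response of the antiviral list and the IFNg response of MHC class I gave r = 0.560. None of these passed, with exact permutation p adjusted over 7 relations between 0.26 and 0.86. In the same order rho was −0.024, −0.119, −0.143, 0.619 and 0.571, with exact permutation p adjusted between 0.26 and 0.98.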

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

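The tests of labels, of an unresponsive culture, of high unstimulated levels and of scaling were chosen after the results were seen, and those of paralogs, depth, length and GC content and other groupings of the libraries before their own values were seen. The results below were picked out because the 8 lines differed by edgeR's F test over lines. That test passed for 7786 genes for IFNb against NS, 11171 for IFNg against NS and 11325 for IFNg against IFNb.

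The antiviral list hardly moved with IFNb in YUMMER1.7. A swap of the unstimulated and IFNb labels would lower H2-K1, H2-D1 and B2m, and the lowest of their log2 fold changes was 0.38. Other interferon genes, picked after their values were seen, moved as a swap predicts. Ifit1 stood at 837 to 1001 CPM unstimulated and 677 to 714 with IFNb, and Gbp2 at 170 to 202 and 124 to 133. The 3 genes argue against a swap but do not settle it. Cultures without any effect of IFNb would show no risen MHC class I genes, and 7 rose. The median unstimulated level of the antiviral list was 75.1 times that of B16.1, the highest of B16.1, KPC.2, LLC and MC38.7, so the small change may in part reflect genes that were already high. It was 15.8 times that of Panc02.3, 3.20 times that of Renca and 1.75 times that of CT26.2, where 33, 35 and 34 of 38 members still rose with IFNb, and why the level was high was not tested.

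The antiviral list was lower with IFNg than with IFNb in KPC.2, LLC and MC38.7 and higher in B16.1, Panc02.3 and YUMMER1.7. Without the Oas, Ifit, Mx, Ifi27, Ifi44 and Ifitm members, 6 of 6 lines kept the direction, but the medians of the fitted changes, used throughout this paragraph without the floor of 3 counts, went from −1.72 to −0.96 in KPC.2, −3.87 to −2.34 in LLC and −3.35 to −1.87 in MC38.7, so reads shared between paralogs are an unlikely sole cause and part of the size may depend on them. A wrong scale in these 3 lines would also lower the GBP and IRG list, whose median was 4.26, 0.93 and 1.78. A first bound of 1 on the lowest median had been missed. The lower quartile of the GBP and IRG list lay at least 2.26 above the upper quartile of the antiviral list. A wrong scale shifts both lists alike and leaves that distance unchanged, and a list raised by IFNg could stay above 0. These values therefore cannot decide on scaling there. In B16.1, Panc02.3 and YUMMER1.7 the lower quartile of the GBP and IRG list lay at least 1.28 above the upper quartile of the antiviral list. A wrong scale would leave this distance unchanged too, so it cannot decide either. With DESeq2 size factors in place of TMM the antiviral medians were −1.74 in KPC.2, −3.91 in LLC and −3.40 in MC38.7. They were 2.03 in B16.1, 0.93 in Panc02.3 and 0.76 in YUMMER1.7, so the direction did not depend on the choice between these 2 scalings. A part of scaling in the size stays open, as does an error common to both scalings, and no biological explanation was tested. Whether the direction would hold at other doses or times was not tested either.

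In Panc02.3 IFNg changed more genes than in any other line, and more fell (2190) than rose (1424), with 1661 and 1500 when each line was fitted alone. With the unstimulated libraries thinned to the depth of the IFNg libraries, 1955 to 1984 genes fell and 1460 to 1486 rose, a ratio of at least 1.33 in 5 thinnings, so part of the excess was lost. After removal of a trend with transcript length and GC content 90.6% of the genes kept a 2-fold change. Lower depth and such a trend are therefore unlikely as sole causes, and no biological explanation was tested.

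The distances between lines below are those of selected genes only, and genes outside the selection spanned more. Each distance covers only the lines with more than 3 counts in both groups. A small distance, as for Cxcl9 with IFNb, may therefore rest on few lines and does not show an equal response in all. For IFNb against NS the distance between the highest and the lowest line in log2 fold change was, among the selected genes, widest for Cxcl10 (11.97), Ifit1 (11.81), Rsad2 (11.53), Oas1a (10.69), Isg15 (9.44), Irf7 (9.41), Mx1 (7.49), Tap1 (7.03) and Nlrc5 (6.62). It was narrower for Lgals3bp (5.84), Cd274 (5.34), Psmb8 (5.28), Cd74 (5.06), H2-Q4 (4.86), Irf9 (4.35), Oas1c (3.92) and H2-K1 (3.74). Smaller distances were those of B2m (3.02), H2-T22 (2.87), Ankrd37 (2.77), Cdkn1a (2.50), H2-D1 (2.31), Socs1 (2.28), Irf1 (2.09), Mki67 (1.72) and Kazald1 (1.44). The smallest were those of Adhfe1 (1.23), Acss2 (1.23), Mapk8ip1 (1.13), Ccdc167 (1.05), Ifnar1 (0.60), Ifngr1 (0.57) and Cxcl9 (0.39).

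For IFNg against NS the distance between the highest and the lowest line in log2 fold change was, among the selected genes, widest for Cd74 (10.64), Irf7 (10.33), Oasl2 (9.87), Igtp (9.54), Gbp3 (9.34), Gbp7 (8.55), Irgm2 (8.52), Tap1 (8.15) and Isg15 (7.86). It was narrower for Cxcl10 (7.79), Gbp2 (7.42), Cxcl9 (7.05), Ifi47 (7.01), Gbp5 (6.90), Ifit1 (6.85), Nlrc5 (6.79), H2-K1 (6.10) and C4b (5.85). Smaller distances were those of Ciita (5.80), Npnt (5.25), Mx1 (5.05), Socs1 (4.99), Rsad2 (4.87), Cd274 (4.29), Irf9 (4.26) and Mki67 (3.94). Next came H2-D1 (3.87), B2m (3.82), Tns1 (3.48), Psmb8 (3.43), S100a4 (3.4), Sema4g (3.37), Gamt (3.25), Irf1 (3.16) and Cdkn1a (2.11). The smallest were those of Pgap1 (2.08), Kazald1 (1.80), Fam171a2 (1.77), Ifnar1 (0.69) and Ifngr1 (0.45).

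For IFNg against IFNb the distance between the highest and the lowest line in log2 fold change was, among the selected genes, widest for Apol10b (8.22), Gbp4 (8.14), a predicted locus (8.06), Gm4841 (7.57), a predicted locus (7.05), Tgtp1 (6.35), C4b (5.93), Iigp1 (5.34) and Batf2 (4.58). It was narrower for Gbp2 (4.39), Tns1 (3.63), Klhdc7a (3.22), Arap3 (2.84), Gdpd5 (2.75), Ankra2 (2.52), Acsbg1 (2.47), Rflnb (2.09) and Masp1 (1.56). The smallest was that of Pik3r3 (1.51). On the mean of the lines 1 of these predicted loci and Acsbg1 lost their pass in 1 of 47 refits without a library.

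Some genes departed in 1 line from the mean of the other 7 lines, by which they were chosen and tested. The departures printed here are against the mean of the other lines with more than 3 counts in both groups, which can be few. They were not tested. A small one, as for Phf11a (−0.24), Reck (0.60) or Plxdc1 in YUMMER1.7 (0.91), is not the value that passed. With IFNb, the departures were in B16.1 for Apol9b (6.59), Apol9a (5.79) and Phf11a (−0.24), CT26.2 for Gm45647 (1.44), Calhm5 (1.91) and Oas2 (−3.21) and KPC.2 for Ifit1 (6.5), Tap1 (5.04) and Gm14421 (−3.03). The next were in LLC for Cxcl10 (9.24), Rsad2 (8.72) and Ccnb1ip1 (−3.50), MC38.7 for Ifi211 (6.74), Trim30a (6.90) and Kif21b (−2.68) and Panc02.3 for Reck (0.60), Loxl2 (1.55) and Ifit1 (−3.99), and in Renca for Plxdc1 (2.66), Rbms3 (1.75) and Oas2 (−3.38) and YUMMER1.7 for Gm14434 (2.40), Plxdc1 (0.91) and Zbp1 (−4.70). With IFNg, the departures were in B16.1 for Apol9b (8.76), Ccl5 (9.75) and Pgk1-rs7 (−5.20), CT26.2 for Pcdhga2 (2.26), a predicted locus (3.56) and Gm12185 (−4.01) and KPC.2 for Gm10698 (3.01), Tap1 (6.28) and Pde1b (−2.45). The next were in LLC for Gbp3 (4.66) and Gbp2 (4.21), MC38.7 for Irgm2 (2.86), Rtp4 (2.69) and Cd74 (−5.54) and Panc02.3 for Avil (6.04), Pcdhgc4 (4.77) and Bmf (−5.37), and in Renca for Gm4202 (2.31) and a predicted locus (2.46) and YUMMER1.7 for Apol7e (4.52), Slit1 (1.48) and Iigp1 (−6.35). With 1 library left out, the change within its line lost its pass in 5 of 6 refits for the predicted locus in CT26.2, 4 of 6 for Calhm5, 2 of 6 for Pde1b and 1 of 6 for Gm14421 and Pcdhgc4. With all libraries that change did not pass with IFNb for Phf11a (adjusted p = 0.42), Gm45647 (adjusted p = 0.53), Reck (adjusted p = 0.73) and Rbms3 (adjusted p = 0.15), nor in YUMMER1.7 for Gm14434 (adjusted p = 0.11), Plxdc1 (adjusted p = 0.20) and Zbp1 (adjusted p = 0.19). With IFNg it did not pass for Pcdhga2 (adjusted p = 0.41), Gm10698 (adjusted p = 0.19), Cd74 (adjusted p = 0.90), Gm4202 (adjusted p = 0.21), the predicted locus in Renca (adjusted p = 0.22) and Slit1 (adjusted p = 0.47). Its sign turned in 1 refit for Phf11a and Gm45647. No value is given for H2-Eb1 in LLC and Insrr in Renca, which had more than 3 counts in both groups of that line alone.

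Other groupings of the libraries within lines gave fewer genes than the labels. Of 100 groupings, the labels among them, 1 reached the number for the mean of the lines: 272 for IFNb against NS, with at most 63 in the others, 525 for IFNg against NS, with at most 102 in the others and 327 for IFNg against IFNb, with at most 80 in the others. For the difference between lines 1 of 100 did so: 7786 for IFNb against NS, with at most 7100 in the others, 11171 for IFNg against NS, with at most 6904 in the others and 11325 for IFNg against IFNb, with at most 9829 in the others. The other groupings mix the 2 treatments unevenly within lines, which itself makes lines differ and widens the spread within groups. They are no reference without an effect, so they cannot decide whether the numbers for the difference between lines exceed chance. Within a line only 10 groupings exist, too few for a share under 0.05. The number with the labels and the highest other number were, for IFNb against NS, B16.1 (715, 9), CT26.2 (59, 25), KPC.2 (218, 144), LLC (1138, 0), MC38.7 (692, 114), Panc02.3 (211, 13) and YUMMER1.7 (27, 0). For IFNg against NS they were B16.1 (3119, 3), CT26.2 (289, 2), KPC.2 (1124, 1), MC38.7 (218, 0), Panc02.3 (3614, 422) and YUMMER1.7 (633, 1). For IFNg against IFNb they were B16.1 (2293, 5), CT26.2 (158, 56), KPC.2 (776, 46), MC38.7 (497, 20), Panc02.3 (3318, 296), Renca (236, 4) and YUMMER1.7 (591, 0). In each of these 1 of 10 groupings, that of the labels, reached the number.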

How the results depend on the processing

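All alternatives were chosen before the data were examined, except the relations with list medians bounded at 3 counts, chosen after seeing the data. Labels give no batches, groups hold 2 or 3 libraries, depth goes down to the 668355 counts of KPC.2 with IFNb (replicate 3), and reads of Gbp, Iigp1, Tgtp1, Apol9, Oas1 and H2 genes may be divided between relatives or, in the BALB/c lines CT26.2 and Renca, be counted less well against a C57BL/6 reference. No list, relation or gene followed through the alternatives changed sign past its threshold. Genes named only as members of a list were not followed. More genes rose than fell with IFNb in Renca with the block (106 and 89), no filter (170 and 144) and each line alone (114 and 108), against 111 and 120, and KPC.2 had 497 genes higher and 787 lower between the cytokines with limma-voom, against 492 and 284. DESeq2, DESeq2 size factors and the replicate block kept 35 of 35 counts of genes within 1.5 times, limma-voom 32, no filter 29 and each line alone 25 of 28. Without the filter, IFNb against NS gave 133 genes in CT26.2, 320 in Panc02.3 and 135 in YUMMER1.7, IFNg against IFNb gave 255 in CT26.2, and 8 (IFNb) and 21 (IFNg) genes fell in at least 4 lines. With each line alone, IFNb against NS gave 36 in CT26.2, and 1 (IFNb) and 5 (IFNg) genes fell in at least 4 lines. With limma-voom, IFNb against NS gave 43 in YUMMER1.7, and IFNg against IFNb gave 1284 in KPC.2 and 852 in MC38.7. The cause was not tested.

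With an estimated correlation camera kept 67 of 78 list results, and the adjusted p was 0.071 (complement), 0.16 (proliferation), 0.11 (glycolysis) and 0.16 (mitochondrially encoded) for IFNb, 0.053 (feedback), 0.16 (proliferation) and 0.29 (mitochondrially encoded) for IFNg, and 0.16 (nucleic acid sensing), 0.40 (MYC), 0.34 (glycolysis) and 0.15 (extracellular matrix) between the cytokines. With the replicate block it kept 77, with 0.065 for feedback with IFNg. The cause was not tested. Size factors kept 78 of 78. The 5 relations given kept their side of 0.05 under each alternative. Of the named genes, DESeq2 kept 171 of 172, size factors and the block 174 of 174, limma-voom 171, no filter 169, each line alone 39 of 41 and leaving out a library 340 of 348 calls. Genes named only as members of a list were not among these. Replicates of one number did not pair: over 68 pairs the median correlation was 0.005 (−0.603 to 0.419), 18 passed 0.1, in no line did all, and the same number was the best match in 25.

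Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, the counts ran as follows. IFNb against NS: B16.1 632 to 678, CT26.2 53 to 60, KPC.2 204 to 218, LLC 1063 to 1095, MC38.7 596 to 680, Panc02.3 189 to 207, Renca 188 to 236 and YUMMER1.7 18 to 29. IFNg against NS: B16.1 2898 to 3149, CT26.2 262 to 270, KPC.2 1000 to 1055, LLC 340 to 378, MC38.7 200 to 209, Panc02.3 3415 to 3711, Renca 232 to 309 and YUMMER1.7 553 to 617. IFNg against IFNb: B16.1 2096 to 2353, CT26.2 149 to 165, KPC.2 652 to 759, LLC 598 to 703, MC38.7 415 to 478, Panc02.3 3153 to 3379, Renca 194 to 238 and YUMMER1.7 517 to 565. On the means of the lines they ran 266 to 278, 514 to 540 and 312 to 341, and for differences between lines 7414 to 8064, 10952 to 11235 and 11161 to 11411. Genes risen in all 8 lines stayed at 0 (IFNb) and ran 71 to 76 (IFNg), and genes fallen in at least 4 lines 1 to 3 and 8 to 13, the former reaching 1 without CT26.2 IFNb replicate 1, CT26.2 NS replicate 1 or LLC IFNb replicate 3. Genes changed by both cytokines ran 189 to 204.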

Other observations

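The antiviral list, as a median over members, reached similar levels with IFNb in lines that started far apart. This pattern was picked out after the levels were seen and not tested. Single members could lie further apart, as Ifit1 with IFNb at 66.7 to 76.1 CPM in Panc02.3 and 729 to 746 in LLC. The median over members of the list differed 198-fold between the highest and the lowest unstimulated line, YUMMER1.7 (177 CPM) and KPC.2 (0.892 CPM), and 22.7-fold with IFNg. With IFNb the highest line was 3.22 times the lowest. With IFNg the list reached 324 CPM in B16.1, against 87.1 with IFNb, and 286 CPM in YUMMER1.7, against 161. A correlation of unstimulated level with response was computed first and dropped, since the response contains the unstimulated level.

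Unstimulated YUMMER1.7 libraries held reads of Ifnb1, the gene of IFNb itself, picked out after the values were seen and not tested. They held 35 counts over 3 libraries, against 2 over the other 20 unstimulated libraries. YUMMER1.7 held 11 counts with IFNb and 78 with IFNg, and all other lines 13 together. No secreted protein was measured.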
